A study of Homo sapiens with 6 samples.

How the data were processed

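RNA sequencing libraries from cells labelled SH-SY5Y were compared in 2 groups of 3, transfected with a GFP vector or with a GFP-CCNB1IP1 vector, per the labels. Libraries were made from polyadenylated RNA captured on oligo-dT beads and primed at random, per the labels' protocols. Strand was not stated, so reads of a gene and of an overlapping or antisense gene may not be separable. HISAT2 and Cufflinks are named without versions in the submitters' processing notes. The deposited values are FPKM per gene, with the lower and upper bounds of a confidence interval and a status, per the file headers, in 1 table per library with the replicates kept apart. The genome build and annotation release are not given in the sources used here. Gene names, identifiers and chromosomes were taken from the tables, which carry those of mouse; starts were read as counted from 0 and are given from 1.

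Each table had 53537 rows, and 38 identifiers that stood on several rows were summed to give 53492 genes. Genes were tested on log2(FPKM + 1) where the mean FPKM over the 6 libraries was at least 1, which left 13231 genes; Ccnb1ip1 fell below the filter and was read from the fit of all 26841 genes above 0 in any library. FPKM were used as deposited, with no further scaling. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The test was limma 3.58.1 in R 4.3.3, with a mean-variance trend and no block, and p-values were adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. An exact two-sided permutation test of 3 against 3 cannot give a p below 0.1, so none was used for single genes. A single gene, Phf3, had a status other than OK.

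Depth was not given. The fragments behind a value were estimated as the square of the FPKM over its standard error, taking the deposited upper bound as 2 standard errors above the FPKM. Of implied values from 0.5 to 8.5, between 51.4 and 54.9% lay within 0.05 of a whole number, so these are estimates and no count test was run. Relative depth came from the fragments per FPKM of 3234 to 4269 genes with 5 to 50 implied fragments, and the shallowest library, GFP-CCNB1IP1 replicate 2, was at 0.744 of the GFP mean. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.985 to 0.988 within groups and 0.984 to 0.986 between them.

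Lists of genes were fixed with human symbols before the data were examined, and 31 lists with 895 symbols were written down. Symbols were matched to the mouse names without regard to case, with 35 differing names added after the tables were seen, and 863 matched. Where a symbol stood on several genes the one with the highest mean was used. Lists with at least 5 measured genes were tested with camera from limma, two-sided, with a preset correlation of 0.01, and 26 could be tested. Camera with an estimated correlation and fry, which tests whether a list's genes move one way without comparing them with other genes, were run beside it. Random lists of the same size, 10000 per list, were drawn from 20 bins of mean expression.

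Named genes followed a rule fixed beforehand. It takes CCNB1IP1, then up to 12 genes per direction among those that pass without overlap of the groups, or the 5 smallest p-values in a direction where none passes, then up to 4 members with the smallest p-values of each list described, and cyclin B1 and CDKN1A always. Some list members that the rule takes are not reported here. After the results were seen, with them the changes of sign that low members of other lists showed between settings, description by members was limited to the 10 lists that passed. Ccna2, Pttg1, Gadd45a, Ddit3, Lfng, Rbpj, the rodent-lineage genes and the Hoxc genes fall outside the rule and were chosen after their values were seen.

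The test was checked on simulated data for the same comparison, with 13231 genes and 5 draws. It recovered 73.1% of genes changed by 0.5 on the log2 scale, 94.6% of those changed by 1 and 99.4% of those changed by 2, with 51 false calls in all draws. The changed genes were drawn only from those well above the filter in the GFP libraries, so recovery of low genes was not tested. Each gene's noise was set from its own spread in these libraries, so the shares may not hold for the real test. A list shifted by -0.25 was called in 5 of 5 draws, with the preset and with the estimated correlation, and 0 of 125 unshifted lists were called. The simulated noise was independent between genes, so it does not test the effect of correlation within a list.

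The alternatives tried were pseudocounts of 0.1 and 5, no filter and a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, TPM, loci under 300 bases left out with the rest rescaled to the same sum, a block for the replicate number, limma without the trend and with a robust prior, a test against a fold change of 1.5, genes with another status left out, and each library left out in turn. Added after the data were seen were leaving out predicted genes and pseudogenes, an implied mean of at least 10 fragments, a mean FPKM of at least 10, a robust prior without the trend, that prior together with a mean FPKM of at least 5, and leaving out genes held by more than 1 list. Several list members, among them Cdt1, Gins2 and Tubb3, were not analysed here.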

Results

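Transcript levels were measured by RNA sequencing of polyadenylated RNA in 6 libraries, 3 labelled GFP and 3 labelled GFP-CCNB1IP1. The labels give the cells as SH-SY5Y, a human neuroblastoma line that grows with sympathetic neuron-like features, and name transfection with an expression vector for green fluorescent protein (GFP) alone or for GFP joined to CCNB1IP1. CCNB1IP1, also called HEI10, is an E3 ubiquitin ligase named for its binding to cyclin B1 and known for its part in meiotic crossing over. Values were FPKM, the fragments assigned to a gene scaled by its transcript length and by the size of the library, for 53492 genes. The tables give no read totals; relative depth, read from the deposited confidence intervals with the mean of the GFP libraries set at 1, was 0.993, 1.06 and 0.950 in GFP replicates 1 to 3 and 0.988, 0.744 and 1.04 in GFP-CCNB1IP1 replicates 1 to 3. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

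The gene tables carried mouse gene names and 19 numbered chromosomes, and 0 of the 53492 identifiers matched the 62700 of a human gene table. Genes of rodent lineages were abundant in every library. H2-K1, a mouse class I histocompatibility gene, had a mean of 385 FPKM in the GFP libraries and 387 in the GFP-CCNB1IP1 libraries, and H2-D1 had 241.5 and 241.3 FPKM. Rhox5, a homeobox gene of the X-linked rodent cluster, had 162.4 and 161.8 FPKM, and Ctla2a had 241.9 and 240.2 FPKM. Of 20 such genes, chosen after the data had been seen, 16 were at 10 FPKM or more in each of the 6 libraries, with library medians from 18.0 to 20.9 FPKM. Neighbouring Rhox2 and Rhox4 copies and Apol9a and Apol9b resemble each other closely, so how reads were divided among them is uncertain. All values given here are therefore those of mouse genes, in libraries whose labels name a human line.

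**Figure D1:**
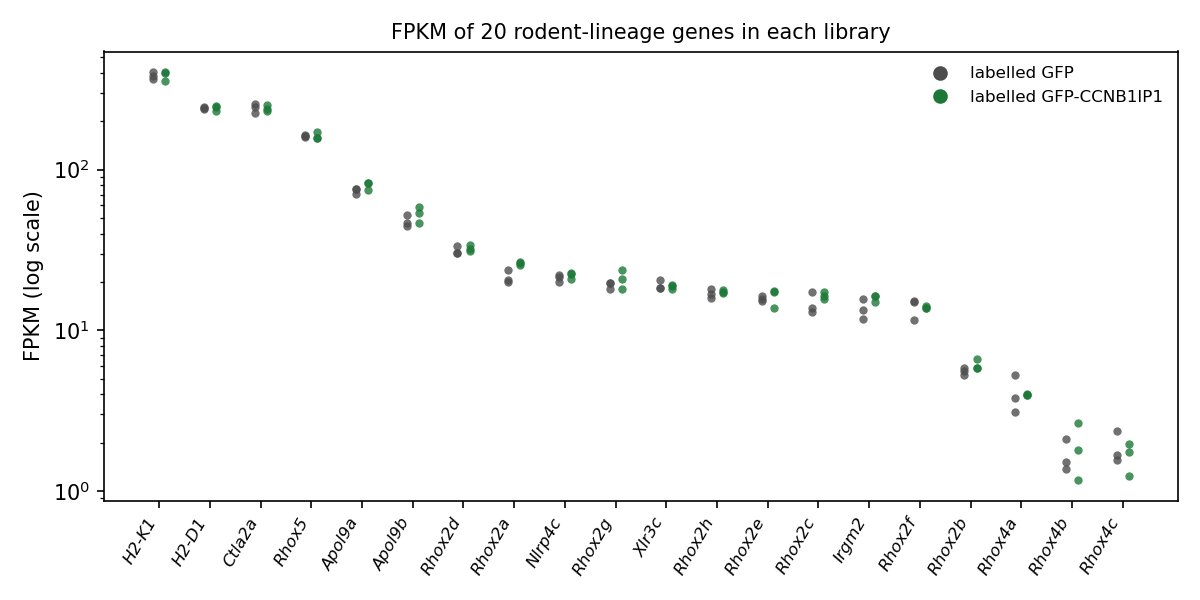
FPKM (log scale) of 20 rodent-lineage genes in each library, with 1 point per library and the 2 labelled groups in separate colours. In each library 16 of the 20 genes lie at 10 FPKM or more, from H2-K1 near 385 FPKM downward.

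The first comparison was the level of CCNB1IP1 itself, which would check the labels. The mouse gene Ccnb1ip1 (ENSMUSG00000071470.5, chromosome 14, 51026705 to 51045189, genome build not given in the sources used here) was close to 0 in both groups. It had 0.0334, 0.125 and 0.0698 FPKM in the GFP libraries, and 0, 0.133 and 0.191 FPKM in the GFP-CCNB1IP1 libraries. The difference on the log2(FPKM + 1) scale was 0.039 (SE 0.073; limma, adjusted p = 0.875). The introduced CCNB1IP1 coding sequence, taken here to be human, and the GFP sequence were not analysed here. If the introduced sequence was human, these values neither bear out nor contradict the labels. If it was of mouse, values this near 0 in the libraries labelled GFP-CCNB1IP1 would go against the labels. Its species was not checked here. The groups are therefore described as the libraries labelled GFP and those labelled GFP-CCNB1IP1.

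The second comparison asked which genes differed between the libraries labelled GFP-CCNB1IP1 and those labelled GFP. A single gene passed the test, the unnamed gene model Gm20305, which was higher in the GFP-CCNB1IP1 libraries. Genes of chaperones and of dividing cells had the smallest p-values among lower genes, and none of them passed. Hspa1b, an inducible heat shock protein 70 gene, had 7.22 ± 1.81 FPKM (SD, n = 3) in the GFP libraries and 1.91 ± 0.165 in the GFP-CCNB1IP1 libraries, and Mki67, the gene of the proliferation antigen Ki-67, had 28.4 ± 0.641 and 20.7 ± 1.31.

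Gm20305 (ENSMUSG00000103979.2) lies on chromosome 1, from 180681847 to 180682023. It was listed at 0 in all 3 GFP libraries and at 11.9, 8.29 and 21.2 FPKM in the GFP-CCNB1IP1 libraries (limma, adjusted p = 0.0126). The deposited intervals imply only 1.99, 1.0 and 4.0 fragments behind those values, since a gene this short reaches a high FPKM from very few fragments. No fold is given because the GFP group is at 0. The adjusted p of Gm20305 was 0.177 with a pseudocount of 5, 0.171 with no filter on low values, 0.057 with the replicate number as a block, 0.0609 in limma without the trend and 0.0564 with a robust prior and no trend. It was 0.132 without GFP replicate 2, 0.115 without GFP replicate 3 and 0.0601 without GFP-CCNB1IP1 replicate 1. Leaving out loci under 300 bases, predicted genes, genes with an implied mean under 10 fragments or genes with a mean FPKM under 10 took Gm20305 itself out of the test.

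Of 13231 genes tested, 1 was higher and 0 were lower at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1502 genes, 739 higher and 763 lower, where 662 would be reached by chance on average. The groups did not overlap for 2329 genes, or 17.6%, against the 10% that chance gives on average for 3 against 3. Genes are not independent, so either count can stray far from its average by chance. The median log2 fold change over all genes was 0.004.

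The 5 lower genes with the smallest p-values were Hspa1b, Hspa1a, Tk1, Mki67 and Cdc25b, and none passed. Hspa1b (ENSMUSG00000090877.4, chromosome 17, 35175412 to 35178214) had a log2 fold change of -1.48 (SE 0.156, adjusted p = 0.0987). Its near-identical neighbour Hspa1a had 2.48 ± 0.502 and 0.554 ± 0.137 FPKM, with a log2 fold change of -1.16 (SE 0.150, adjusted p = 0.176); how reads were split between this pair is uncertain. Tk1, a thymidine kinase of DNA precursor synthesis, had 52.2 ± 2.38 and 37.7 ± 2.23 FPKM. Cdc25b, a phosphatase that activates cyclin-dependent kinases, had 11.7 ± 0.411 and 8.38 ± 0.163 FPKM. Hspa1b passed the threshold when values were rescaled to TPM (adjusted p = 0.0493), without GFP replicate 1 (adjusted p = 0.0341), and when predicted genes and pseudogenes were left out of the test (adjusted p = 0.0475).

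Cyclin B1 and the cell cycle inhibitor p21 were to be given whatever their result. Ccnb1 (ENSMUSG00000041431.17, chromosome 13, 100915158 to 100923078) had 25.9 ± 3.72 FPKM in the GFP libraries and 18.5 ± 1.99 in the GFP-CCNB1IP1 libraries (SD, n = 3), a log2 fold change of -0.46 (SE 0.115, limma, adjusted p = 0.270). Cdkn1a (ENSMUSG00000023067.15, chromosome 17, 29309950 to 29319701) had 36.8 ± 4.47 and 40.3 ± 3.86 FPKM, a log2 fold change of 0.131 (SE 0.098, adjusted p = 0.657).

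**Figure D2:**
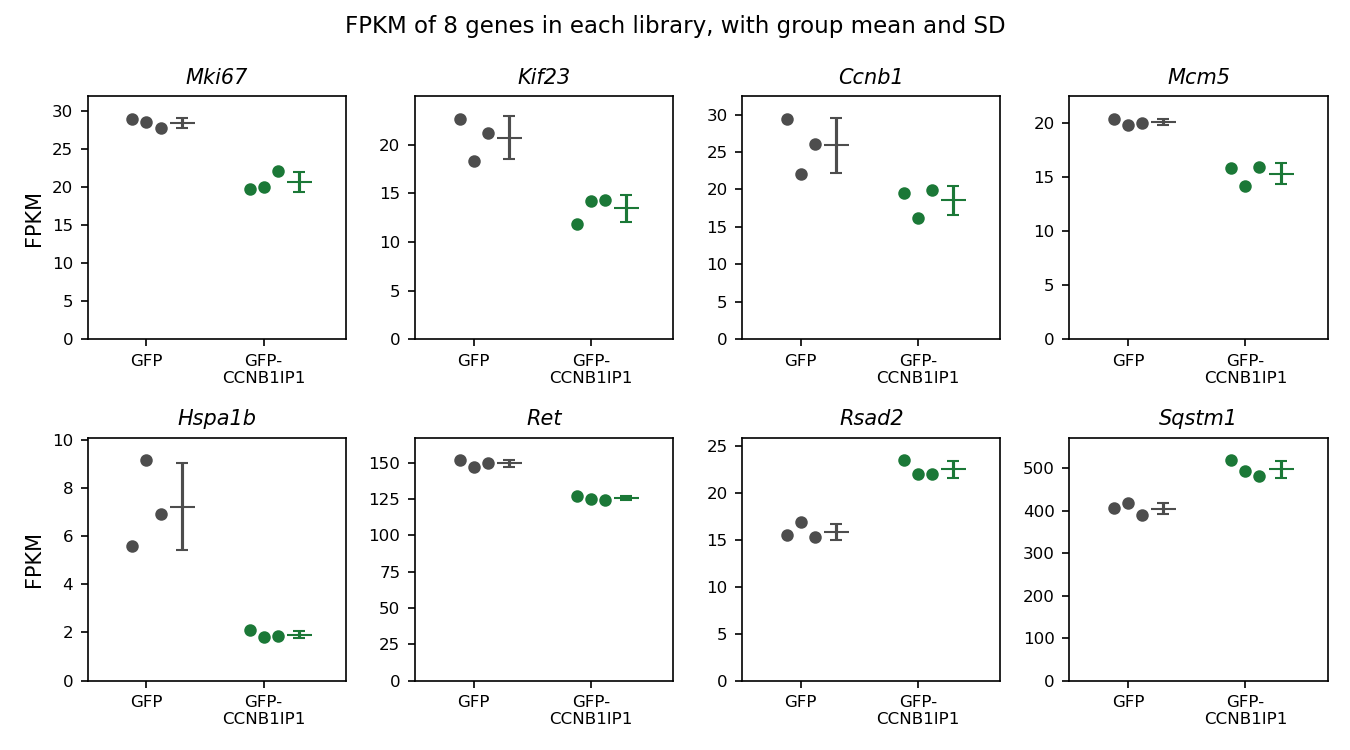
FPKM of 8 genes in each library (points), with the group mean and SD beside them, in the libraries labelled GFP and those labelled GFP-CCNB1IP1. The groups do not overlap for any of the 8 genes, and none of the 8 passed the test over all genes. Apart from Ccnb1, the 8 were named for their small p-values, so the lack of overlap is no separate evidence. Among all genes tested, 17.6% had groups that did not overlap.

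The third comparison asked whether gene lists fixed before the data were examined moved as groups. By camera with a preset correlation of 0.01 between genes, genes of mitosis, DNA replication, chaperones, noradrenergic identity and neuronal differentiation were lower in the libraries labelled GFP-CCNB1IP1, and interferon response, amino acid response, lysosomal, proteasome and NF-kB genes were higher. These were 10 of the 26 lists tested, and with a correlation estimated from these libraries 0 of the 26 passed (adjusted p from 0.294 to 0.695 for the 10). With fry, 1 list passed. In splits of the libraries that mix the groups, camera with the preset correlation still called from 3 to 8 lists. Such splits keep part of any difference between the groups, so these counts are not those of chance alone. The list median farthest from 0 was that of the G2/M genes, at 0.817 times the GFP value on the FPKM + 1 scale.

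G2/M genes fell as a group (camera, adjusted p = 2.741e-17). The call did not hold with an estimated correlation (adjusted p = 0.401) or with fry (adjusted p = 0.121). Of 40 measured members, 39 were lower, with a median log2 fold change of -0.29. At an unadjusted p under 0.05 there were 23 lower members and 0 higher, 17 passed when adjusted over the list alone, and 0 passed over all genes tested. The mitotic kinesin gene Kif23 had 20.8 ± 2.23 FPKM in the GFP libraries and 13.5 ± 1.41 in the GFP-CCNB1IP1 libraries, and Kif20a had 9.62 ± 0.746 and 6.84 ± 0.361. Ccna2, the cyclin A2 gene, had means of 19.8 and 14.9 FPKM. Pttg1, the securin gene, was the 1 member with a positive log2 fold change.

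S phase and DNA replication genes also fell as a group (camera, adjusted p = 3.726e-15). With an estimated correlation the adjusted p = 0.294, and with fry the adjusted p = 0.0987, so neither kept the call. All 38 measured members were lower, with a median log2 fold change of -0.22, and 13 passed when adjusted over the list alone against 0 over all genes tested. Mcm5, a subunit of the replicative helicase, had 20.1 ± 0.277 and 15.3 ± 0.962 FPKM. Its helicase partner Cdc45 had 11.6 ± 0.282 and 8.41 ± 0.635 FPKM, the flap endonuclease gene Fen1 had 17.6 ± 1.099 and 13.9 ± 0.339, and the transcription factor gene E2f1 had 22.3 ± 0.560 and 18.6 ± 1.19.

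Heat shock and chaperone genes fell as a group (camera, adjusted p = 2.778e-07), with 18 of 19 measured members lower and a median log2 fold change of -0.136. Neither an estimated correlation (adjusted p = 0.294) nor fry (adjusted p = 0.0696) kept this call. Hspa1b, Hspa1a and Cryab passed when adjusted over the list alone, and 0 members passed over all genes. Cryab, a small heat shock protein gene, had 43.5 ± 4.20 and 34.7 ± 2.09 FPKM, and Hsph1 had 102.8 ± 9.25 and 85.9 ± 7.73.

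Genes of noradrenergic neuroblastoma identity fell as a group by a small amount (camera, adjusted p = 0.00332), with 16 of 21 measured members lower and a median log2 fold change of -0.070. The call was lost with an estimated correlation (adjusted p = 0.294), and this was the 1 list that passed with fry (adjusted p = 0.0345). The receptor tyrosine kinase gene Ret had 149.6 ± 2.43 and 125.5 ± 1.52 FPKM, and the secretory granule gene Chgb had 467.9 ± 29.3 and 359.1 ± 34.3. Slc18a2, a vesicular monoamine transporter gene, had a log2 fold change of -0.22 (SE 0.054). Ret, Chgb and Slc18a2 passed when adjusted over the list alone, and 0 members over all genes.

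Neuronal differentiation and synapse genes fell as a group by a similarly small amount (camera, adjusted p = 0.00551), with 21 of 26 measured members lower and a median log2 fold change of -0.058. That call was lost with an estimated correlation (adjusted p = 0.503) and with fry (adjusted p = 0.194). Syn2, a synaptic vesicle gene, had 75.7 ± 2.65 and 63.1 ± 2.36 FPKM. The cell adhesion gene Ncam1 had 37.5 ± 3.02 and 29.8 ± 0.665 FPKM, L1cam had 129.0 ± 7.24 and 108.3 ± 4.67, and the vesicle calcium sensor gene Syt1 had 38.7 ± 1.28 and 34.4 ± 0.204. Syn2, Ncam1 and L1cam passed when adjusted over the list alone, and 0 members over all genes.

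Interferon response genes rose as a group (camera, adjusted p = 1.408e-07), with 29 of 33 measured members higher and a median log2 fold change of 0.142. It did not pass with an estimated correlation (adjusted p = 0.503) or with fry (adjusted p = 0.194). The antiviral gene Rsad2 had 15.9 ± 0.868 and 22.5 ± 0.881 FPKM, and Oas3 had 4.16 ± 0.462 and 6.05 ± 0.322; this pair passed when adjusted over the list alone, and 0 members passed over all genes. Parp14 had 7.74 ± 0.754 and 9.81 ± 0.320 FPKM, and the ubiquitin-like modifier gene Isg15 had 244.3 ± 13.1 and 275.7 ± 7.97. Without GFP replicate 1 the list median was 0.219.

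Amino acid response genes, targets of the transcription factor ATF4, rose as a group (camera, adjusted p = 0.00177), with 24 of 28 measured members higher and a median log2 fold change of 0.093. An estimated correlation ended the call (adjusted p = 0.695), as did fry (adjusted p = 0.346). Cebpb had 59.7 ± 3.70 and 72.8 ± 3.76 FPKM, and the cystine transporter gene Slc7a11 had means of 14.9 and 18.5 FPKM. Gars, a glycyl-tRNA synthetase gene, had 168.0 ± 7.73 and 188.0 ± 2.72 FPKM, and Asns, the asparagine synthetase gene, had 229.2 ± 4.46 and 246.2 ± 6.57. No member passed when adjusted over the list alone. Without GFP replicate 2 the list median was 0.023 and the adjusted p = 0.282.

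Autophagy and lysosome genes rose as a group (camera, adjusted p = 0.0121), with 23 of 31 measured members higher and a median log2 fold change of 0.059. Both an estimated correlation (adjusted p = 0.695) and fry (adjusted p = 0.314) ended the call. Sqstm1, the gene of the autophagy receptor p62, had 405.0 ± 13.5 and 497.7 ± 19.9 FPKM and was the 1 member that passed when adjusted over the list alone. The lysosomal protease gene Ctsb had means of 82.9 and 94.0 FPKM and Npc2 had 25.7 ± 0.754 and 29.1 ± 1.68, while Becn1, which starts autophagosome formation, went the other way with 64.8 ± 3.52 and 57.2 ± 2.69. The adjusted p of the list was 0.149 without GFP replicate 1 and 0.0503 with a mean FPKM of at least 10, and its median was 0.090 without GFP replicate 2.

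Proteasome and ubiquitin genes rose as a group by a small amount (camera, adjusted p = 0.0128), with 28 of 32 measured members higher and a median log2 fold change of 0.057. This list passed neither with an estimated correlation (adjusted p = 0.695) nor with fry (adjusted p = 0.314). The proteasome subunit genes Psmb5 and Psmc2 had log2 fold changes of 0.133 (SE 0.054) and 0.114 (SE 0.048), while Psmd1 had 37.7 ± 0.437 and 34.6 ± 1.43 FPKM. No member passed when adjusted over the list alone. The adjusted p of the list was 0.0591 without GFP replicate 2, 0.0578 without GFP replicate 3 and 0.130 without GFP-CCNB1IP1 replicate 1, where its median was 0.037.

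NF-kB and inflammatory cytokine genes rose as a group (camera, adjusted p = 0.0195), with 15 of 17 measured members higher and a median log2 fold change of 0.058. With an estimated correlation (adjusted p = 0.695) and with fry (adjusted p = 0.443) the list did not pass. Csf1 had 10.9 ± 0.121 and 13.5 ± 0.207 FPKM, Bcl3 had 2.51 ± 0.574 and 4.15 ± 0.191, and the cytokine gene Il6 had 22.6 ± 2.20 and 27.4 ± 0.787; these 3 passed when adjusted over the list alone, and 0 members over all genes. Ier3 had 39.9 ± 9.61 and 46.2 ± 0.772 FPKM, and its groups overlapped. The adjusted p of the list was 0.374 without GFP replicate 1 (median 0.007), 0.105 without GFP replicate 3, 0.130 without GFP-CCNB1IP1 replicate 1 (median 0.032) and 0.0638 without GFP-CCNB1IP1 replicate 2 (median 0.095), while the median was 0.165 without GFP replicate 2 and 0.126 without GFP-CCNB1IP1 replicate 3. With all libraries kept, the adjusted p was 0.0676 with no filter on low values, 0.0605 and 0.0793 with a mean FPKM of at least 5 and 10, and 0.0587 with members shared between lists left out, and the median was 0.036 with a pseudocount of 5.

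**Figure D3:**
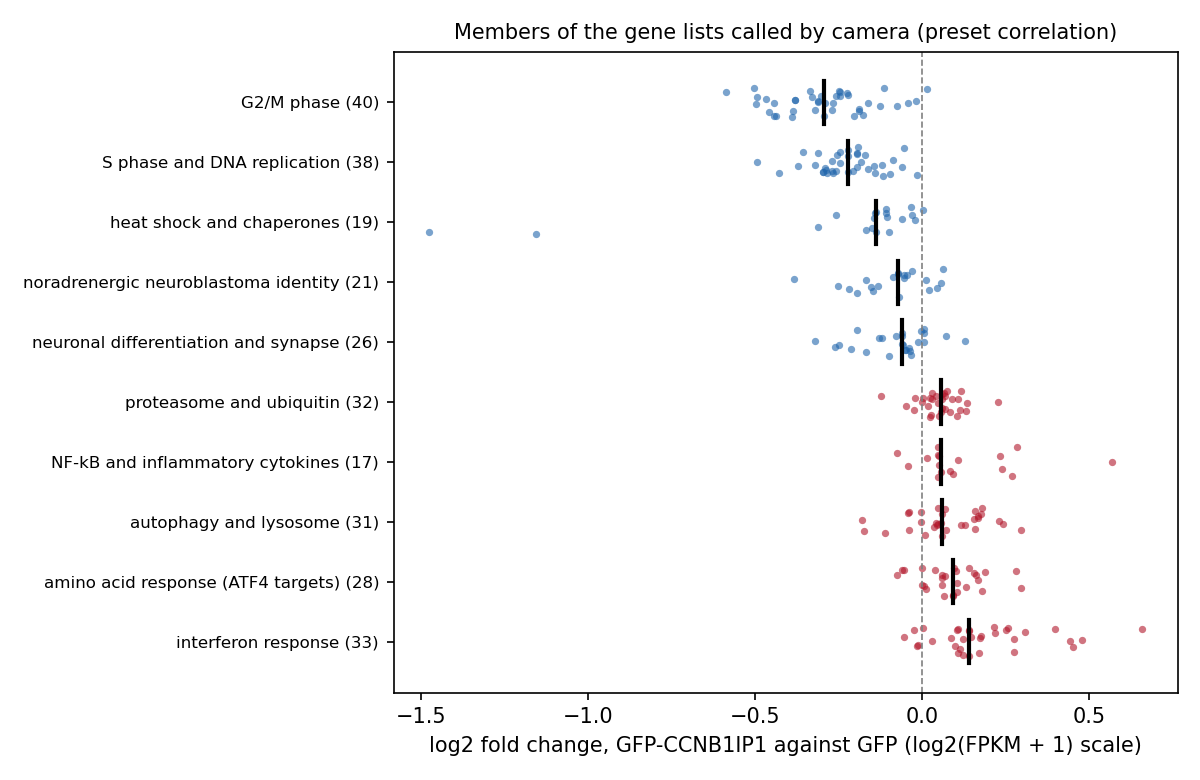
Log2 fold change of each measured member (points) of the 10 lists called by camera with a preset correlation, with the number of measured members after each name and the median as a bar. The medians run from -0.29 for the G2/M genes to 0.142 for the interferon genes, and 0 of the 10 lists passed with an estimated correlation.

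The other 16 tested lists did not pass camera with the preset correlation. The p53 targets had 14 of 24 members higher, a median log2 fold change of 0.036 and an adjusted p = 0.214. Gadd45a, a p53 target of the DNA damage response, had 45.6 and 56.5 FPKM and passed when adjusted over that list alone, as did Ddit3, with 126.0 and 150.8 FPKM, in the unfolded protein response list (list median 0.015, adjusted p = 0.322). In the Notch pathway list Lfng, with 14.3 and 11.6 FPKM, and Rbpj, with 33.9 and 39.6 FPKM, passed in that way in opposite directions, and none of these 4 genes passed over all genes. Medians were 0.052 for mesenchymal neuroblastoma identity (adjusted p = 0.322), 0.053 for neural progenitor genes (0.395), -0.017 for the Notch pathway (0.424), 0.015 for Wnt targets (0.613) and 0.055 for immediate early genes (0.322). They were 0.024 for cholesterol biosynthesis (0.424), 0.050 for glycolysis and hypoxia (0.322), 0.019 for nuclear-encoded oxidative phosphorylation (0.621), 0.030 for cytosolic ribosomal proteins (0.129) and 0.039 for apoptosis regulators (0.553). The extracellular matrix list had a median of -0.028 but a mean of 0.001 (adjusted p = 0.755), and the meiotic recombination list, of which 8 of 34 genes were measured, had a median of -0.010 (adjusted p = 0.493).

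Markers of other cell types were mostly close to 0 FPKM. Endothelial markers had a median log2 fold change of 0.066 over 6 measured genes (adjusted p = 0.597). Glial, epithelial, leukocyte and fibroblast lists had 4 of 18, 1 of 21, 2 of 20 and 4 of 19 matched genes above the filter, too few to test, and their matched genes had median levels of 0.0355, 0.0264, 0.0505 and 0.121 FPKM in the GFP libraries and 0.0342, 0.0206, 0.241 and 0.0400 in the GFP-CCNB1IP1 libraries. The 13 mitochondrially encoded genes had a median log2 fold change of -0.038 (adjusted p = 0.368), and the mitochondrial share of FPKM ran from 15.0 to 18.3% across the libraries. The list named replication-dependent histones had 3 of 22 matched genes measured, too few to test, with median levels of 0.155 and 0.143 FPKM over its matched genes.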

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

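Predicted genes left out, the minimum of 10 fragments, the mean FPKM of at least 10, the robust prior without the trend and its combination with a mean FPKM of at least 5, and shared list members left out were chosen after the data had been seen. The count of called genes, 1 as reported, was 0 in total, 0 higher, and 0 with an absolute log2 fold change of at least 1 with a pseudocount of 5, with no filter on low values, with loci under 300 bases left out and the rest rescaled to the same sum, with limma without the trend, with an implied mean of at least 10 fragments, with a mean FPKM of at least 10, and with the robust prior without the trend. Leaving out loci under 300 bases, genes with few fragments, or genes with a mean FPKM under 10 removes Gm20305 itself; for the others the cause was not tested. Rescaling to TPM gave 2 genes, Gm20305 and Hspa1b, with 1 lower and 2 with an absolute log2 fold change of at least 1. With predicted genes left out there were 0 higher and 1 lower, Hspa1b. Leaving out 1 library gave 0 to 4 called genes, 0 to 2 higher, 0 to 2 lower and 0 to 4 with an absolute log2 fold change of at least 1; the 4 came without GFP replicate 1, 2 came without GFP-CCNB1IP1 replicate 2, and 0 came without GFP replicate 2 or GFP replicate 3. The 4 were Gm20305, Hspa1b, Gm2004 and Gm43940, and the 2 were Gm20305 and Gm10197. Without GFP-CCNB1IP1 replicate 1 the 1 called gene was Gm12208 and not Gm20305. A test against a fold change of 1.5 called 1 gene.

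The 10 called lists were 0 with an estimated correlation and 1 with fry, and 8 to 11 in the other settings that can move them. The trend and the prior of limma do not enter camera, so the settings that change only these repeat other list values and say nothing of their stability. The G2/M median of -0.292 had an adjusted p = 0.401 with an estimated correlation and 0.121 with fry, and the S phase median of -0.221 had 0.294 and 0.0987; in the remaining settings both lists stayed negative and past the threshold, with the G2/M median from -0.376 to -0.202 when 1 library was left out. The estimate takes in how far members of a list move together, which the preset holds at 0.01. For the noradrenergic list the estimate was -0.018, below the preset, and its call was lost too. Members moving together therefore cannot account for every lost call, and the cause was not tested. Among 176 values of the 8 other called lists, without those repeats, 0 changed sign and 29 lost the call, 15 of them with the estimated correlation or fry. The Ccnb1ip1 difference of 0.039 became -0.015 without GFP-CCNB1IP1 replicate 3, with leave-one-out values from -0.015 to 0.111; at levels this near 0 the sign carries no information. That difference had no value with a mean FPKM of at least 5, which leaves the gene out.

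A fit with the replicate number as a block called 0 genes, 0 higher and 0 with an absolute log2 fold change of at least 1, and 10 lists. The samples share only a number: deviations of same-numbered libraries from their group means correlated at 0.023, -0.009 and -0.011 across genes, and 2 of 6 libraries correlated best with their own number. Over 44 named genes and 996 values, 0 changed sign, 3 passed the threshold where the reported value did not, and 8 lost it. A wider follow-up of 121 genes, which also took the leading members of the lists that were not called, gave 20 changes of sign among 2706 values, in 9 genes whose reported log2 fold change was at most 0.186 in size. Depth limits what can be said of short and low genes: Gm20305 rests on at most 4 implied fragments in any 1 library.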

Other observations

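The Hox genes, and the tests of fragments behind Gm20305, of the rodent-lineage genes, of the shallowest library and of library pairs were chosen after the results they bear on had been seen. The Hox genes, which mark position along the body axis, were expressed from 1 cluster. Of 9 Hoxc genes 5 had a mean of at least 1 FPKM, against 0 of 11 Hoxa, 0 of 10 Hoxb and 0 of 9 Hoxd genes, whose highest means were 0.0153, 0.0117 and 0.00566 FPKM. Hoxc6 had 12.7 ± 0.770 FPKM (SD, n = 3) in the libraries labelled GFP and 13.0 ± 0.633 in those labelled GFP-CCNB1IP1, Hoxc10 had 10.9 ± 0.196 and 11.6 ± 1.07, and Hoxc9 had 9.55 ± 0.325 and 9.16 ± 1.72. Hoxc4 had 2.65 ± 0.303 and 1.93 ± 0.377 FPKM, and none of the 5 passed the test (limma, smallest adjusted p = 0.413).

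G2/M genes were lower in the libraries labelled GFP-CCNB1IP1 by camera with a preset correlation, a call lost with an estimated correlation (adjusted p = 0.401) and with fry (adjusted p = 0.121). Under median-of-ratios, quantile and TPM scaling the G2/M median nearest to 0 was -0.293, which argues against a scaling difference. Without the shallowest library, GFP-CCNB1IP1 replicate 2, the median was -0.316; all 9 pairs of 1 library from each group gave a negative median, from -0.492 to -0.082; and 0% of 10000 random lists matched on mean expression had a median as low, which argues against depth, a single deviating library and a trend with expression level. What stays open is chance and culture: the 10 splits of the 6 libraries are too few for a share under 0.05, the real split gave a G2/M median of -0.292 and the other split farthest from 0 gave -0.198, and differences in density or time of harvest, which the labels do not give, were not tested. Each of the other splits mixes the groups, so it keeps part of any difference between them. The transfection, which the labels give as the difference between the groups, also stays open and was not tested. Ccnb1ip1 near 0 leaves the labels unchecked with the introduced sequence taken to be human, and would go against them with a mouse sequence.

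The libraries labelled human carried abundant rodent-lineage genes. The lowest library median of the 20 genes was 18.03 FPKM, but that median follows from choosing genes after their values were seen. Rhox5, at 162.4 and 161.8 FPKM, and Ctla2a, at 241.9 and 240.2 FPKM, argue against human reads assigned to a mouse annotation. Such reads would leave these genes near 0, however they were picked. Whether that holds for each of the 20 genes was not checked. Cells of mouse origin stay open: the highest library median was 20.87 FPKM, but genes chosen after their values were seen cannot test this. A mixture with human cells stays open, whether its share differed between libraries or not: the ratio of highest to lowest was 1.16, but FPKM is scaled to each library's own aligned reads and can stay level whatever the share. A mislabelled or exchanged set of tables may be a candidate explanation, and it was not tested.

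The 1 called gene, Gm20305, had at most 4 implied fragments in any library, which is consistent with a few fragments on a very short gene. Splits of the 6 libraries into 3 and 3 are 10, too few for a share under 0.05. The real split called 1 gene and the highest of the others also called 1, with 4 of the 10 splits, the real one among them, calling as many. For lists, the real split called 10 and the highest of the others 8, so no other split called as many. Camera with a preset correlation called from 3 to 8 lists in splits that mix the groups, which keep part of any difference between them.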
